A study of Oryza sativa Indica Group with 10 samples.

How the data were processed

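The series compared whole seedlings of OsbZIP48 over-expression and knock-down rice lines with seedlings carrying empty vectors, in 10 samples of 5 groups with 2 biological replicates each. Per the labels' protocols, seedlings grew in light at 28 °C, and biotin-labelled RNA was prepared from 500 ng of total RNA. The labels give 10 days as the age and the series' design text 7 days, and the extraction protocol names roots where the tissue label is whole seedling. These disagreements were left as they stand.

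The authors deposited 1 table of log2 probe set values, 1 column per array. Per the submitters' processing notes, GCOS and Affymetrix Expression Console 1.4.1.46 were used, and the summarization and normalization method is not given in the sources used here. That the deposited values are log2 was inferred from their range. They were taken as already background-adjusted and normalized, and no further normalization was applied in the main comparisons. The lowest value was 2.440 on the 4 B4NU and OE arrays and 2.441 on the 6 pANDA and KD arrays, and pairs of arrays had 8627 to 12749 identical values within these sets but 5 to 16 between them. The 2 sets were therefore treated as normalized separately. Comparisons with the own vector control stay within a set. The comparison of the vectors, and alternatives with the other vector or both vectors, cross the sets, so vector and set cannot be told apart there. Every column was mapped to a sample, and the depth of an array has no count, so the number of arrays limits the precision.

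The table held 57381 probe sets, of which 123 controls were left out and 57258 tested. The platform annotation paired 22436 probe sets with 1 gene, 95 with several and 34727 with none, which are unnamed here. The 17905 genes were all found in the RefSeq table of assembly ASM3414082v1, which was used for names only, and 2450 had a gene name. Where a locus has several names, 1 is used throughout. A gene was represented by its probe set with the highest mean over all arrays. No probe set was paired with OsbZIP48, so the planned check of the target was not made.

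One linear model over all 10 arrays with a coefficient per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, 5 residual degrees of freedom), and tests were two-sided. Probe sets were called at an adjusted p (Benjamini-Hochberg over all tested probe sets) under 0.05 with no fold cutoff. The labels do not say which vector belongs to which transgene. B4NU was taken as the control of OE and pANDA, an RNA interference vector, as that of the KD groups, before the data were examined. A group was called at the floor where both arrays lay within 0.5 of the lowest value of their set, and the fold against the group's own mean is then a lower bound. Such values have no order among themselves.

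Of 24 gene lists planned before the data were examined, 2 had at least 4 matching genes (6 pathogenesis-related and 6 seed storage genes), because the tables hold no gene descriptions. Another 32 lists of gene symbols, with 772 genes, were therefore written after the annotation tables were seen and before any comparison was computed. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and with an estimated correlation and with fry as alternatives. With the estimated correlation 0 lists passed in any comparison. The planned lists did not pass camera in any comparison, with adjusted p of 0.662 and 0.343 in OE, 0.612 and 0.612 in KD lethal, 0.509 and 0.594 in KD wild-type-like, 0.799 and 0.799 between the KD groups and 0.585 and 0.414 between the vectors, for pathogenesis-related and seed storage genes. With fry the planned pathogenesis-related list passed in OE (0.023), KD lethal (0.0157), between the KD groups (0.0253) and between the vectors (0.00258), but not in KD wild-type-like (0.0949). The planned seed storage list of 6 genes passed with fry in none.

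The genes named were chosen by a rule set before the data were examined. Per comparison, it takes the 8 largest rises and 8 largest falls among called probe sets of 1 named gene whose groups do not overlap, the 3 genes with the smallest p of each passing list, and the called members of the photoreceptor, gibberellin and flowering-time lists. Between the vectors it takes the 3 largest in each direction. A selection of these genes is printed.

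The model was tested on simulated data before use. OE against B4NU was simulated over 57258 probe sets. Changes of 1, 2 and 4 (log2) were recovered in 3.0, 14.9 and 50.0% of the changed probe sets. These were 2, 10 and 33 probe sets, each with the right sign, so most changes of 2-fold and 4-fold size are missed. Beside them stood 9 other calls, a larger share of false calls than the threshold on adjusted p aims at. The calls reported here may therefore hold more false ones than that threshold implies. In the same comparison camera over 17905 genes found the list that had been moved and 0 of 50 random lists. The simulated probe sets varied independently, so this does not test camera for lists of correlated genes.

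Alternatives were quantile normalization, median centring, a filter to the upper part of the probe sets by mean, removal of cross-hybridising probe set types, eBayes with trend and robust, the 4 arrays of the groups compared, the replicate number as a block, a fold cutoff of 1 (log2), 1 probe set per gene, other vector controls, and leaving out each array. A pseudocount was not needed on log2 values. Tests of other splits of the samples and of single outlying samples need larger groups and were not made. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.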

Results

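Transcript levels were measured on 1-colour Affymetrix rice arrays in light-grown seedlings of the Indica cultivar Pusa Basmati 1. The 10 arrays formed 5 groups of 2 biological replicates. The groups were OsbZIP48 over-expression seedlings (OE), the empty vector B4NU, knock-down seedlings that looked like wild type (KD wild-type-like), knock-down seedlings with a lethal phenotype (KD lethal), and the empty vector pANDA, which is built for RNA interference. OsbZIP48 encodes a bZIP transcription factor related to HY5, a regulator of light-dependent seedling development. The sample labels give an age of 10 days and the series' design text 7 days. The tissue label is whole seedling, whereas the extraction protocol speaks of roots, so the tissue and age are known only to that extent. No probe set was paired with OsbZIP48 in the annotation used here, so its own level was not analysed here and the labels were not checked against it.

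Replicates of one group correlated across probe sets at r = 0.998 in B4NU, 0.997 in pANDA, 0.993 in KD wild-type-like, 0.981 in KD lethal and 0.950 in OE (probe sets are not independent replicates). OE replicate 1 stood apart, with an SD of 0.58 for its log2 difference from OE replicate 2. Averaged over ubiquitin, GAPDH and cyclophilin, the signal of the 3' end minus that of the 5' or middle part was -0.77 in OE replicate 1 and -0.10 in KD lethal replicate 2, and lay between 0.59 and 1.38 on the other arrays. Of the values on an array, 65.6 to 68.8% lay within 0.5 of its lowest log2 value. A group with both arrays in that range is called at the floor here, and a fold against it is given as a lower bound. The B4NU and OE arrays formed 1 separately normalized set and the pANDA and KD arrays another. With 2 arrays per group, the number of arrays limits the precision. The fit gives each probe set 1 spread over all groups, so the p-values for OE do not measure the OE spread alone.

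The comparison of OE with B4NU asks which transcripts differ when OsbZIP48 is over-expressed. Some dehydration genes were higher in OE and some jasmonate and phytoalexin genes lower, and none of these lists passed with an estimated correlation (adjusted p = 0.553 each). The dehydrin gene RAB21 (LOC4350454) stood at 11.69 ± 0.31 in OE and 5.83 ± 0.16 in B4NU (log2 signal, mean ± SD, n = 2), a 58.3-fold difference (adjusted p = 0.000389). Its paralog RAB16B (LOC4350453) rose by 5.50 ± 0.80 (log2, SE; adjusted p = 0.0496), and PM1 (LOC4338635), whose B4NU arrays were at the floor, rose at least 18.4-fold. RAB21 and RAB16B belong to a family of similar genes, so their probe sets may share signal. Of the 9 genes of the dehydration and late embryogenesis list, 3 rose, 0 fell and the median difference was 2.58 (camera adjusted p = 7.78e-09, and adjusted p = 0.553 with an estimated correlation). Nramp1 (LOC4342862), a metal transporter gene, rose 10.8-fold and NAAT1 (LOC9267778), a nicotianamine aminotransferase gene, rose 3.63-fold. Also higher were BHLH063 (6.18-fold), HOX24 (at least 5.89-fold) and ELA3 (4.70-fold).

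Of 33 jasmonate genes, 8 fell and 0 rose in OE, with a median of -0.35 (adjusted p = 4.23e-05, and adjusted p = 0.553 with an estimated correlation). The 8 were 6 JAZ genes, which encode repressors of jasmonate signalling, and 2 lipoxygenase genes. JAZ12 (LOC4348533) fell by 4.58 ± 0.23 (log2, SE; adjusted p = 0.00272), JAZ11 (LOC4331833) fell by 3.53 ± 0.22 and CM-LOX1 (LOC4345993), at the floor in OE, fell at least 19.8-fold. Of 14 diterpenoid phytoalexin genes, 3 fell, 0 rose and the median was -0.18 (adjusted p = 0.00244, and adjusted p = 0.553 with an estimated correlation). They were the cytochrome P450 gene CYP701A8 (LOC4341343), which fell by 4.09 ± 0.26, the diterpene synthase gene KSL7 (LOC4329724; at least 4.62-fold) and CYP76M8. A further P450 gene, CYP71Z7 (LOC4329726), was at the floor in OE and at least 19.3-fold lower than in B4NU. The defence gene PBZ1 (LOC4352491) fell by 3.97 ± 0.43 from 11.2 in B4NU, and NAC068 and CLPD1 fell 10.9-fold and 8.76-fold. All 14 light reaction genes had a negative difference, with a median of -0.60 (adjusted p = 0.0248, and adjusted p = 0.974 with an estimated correlation), but none of them passed alone. For example, PETC, which encodes the Rieske protein, had a difference of -1.12 ± 0.21 (adjusted p = 0.105). Of 29 cellulose and cellulose synthase-like genes, 1 rose, CSLC3 (1.73-fold), with a list median of 0.04 (adjusted p = 0.00244, and adjusted p = 0.737 with an estimated correlation).

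In all, 802 of 57258 probe sets were called in OE at limma's adjusted p under 0.05, 187 higher and 615 lower, and 537 of them differed at least 2-fold. The split depended on each OE array: without replicate 1, 2645 probe sets were called, 1636 higher and 1009 lower, with 658 of the 802 called the same way. Without OE replicate 2 the calls were mostly higher too, and the jasmonate, phytoalexin, cellulose and light reaction lists no longer passed as lists. All 802 probe sets kept their direction without either OE array, but they were chosen with both, which favours this. The count moved with the arrays of the other groups as well. It was 349 without either pANDA array, 451 without either KD wild-type-like array, and 17 when only the 4 OE and B4NU arrays were fitted. In that last fit none of the OE genes named above passed (adjusted p = 0.164 for RAB21). RAB16B, PBZ1, HOX24, ELA3, CLPD1, CSLC3 and CYP76M8 also lost their calls without either pANDA or either KD wild-type-like array, and all of them but ELA3 without either B4NU array. Against pANDA instead of B4NU, the sign of CYP701A8 and PBZ1 turned in OE (0.40 and 0.62, not called). KSL7, CYP71Z7 and CYP76M8 were at the floor in both OE and pANDA, so none of the phytoalexin falls named here was seen against pANDA.

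**Figure D1:**
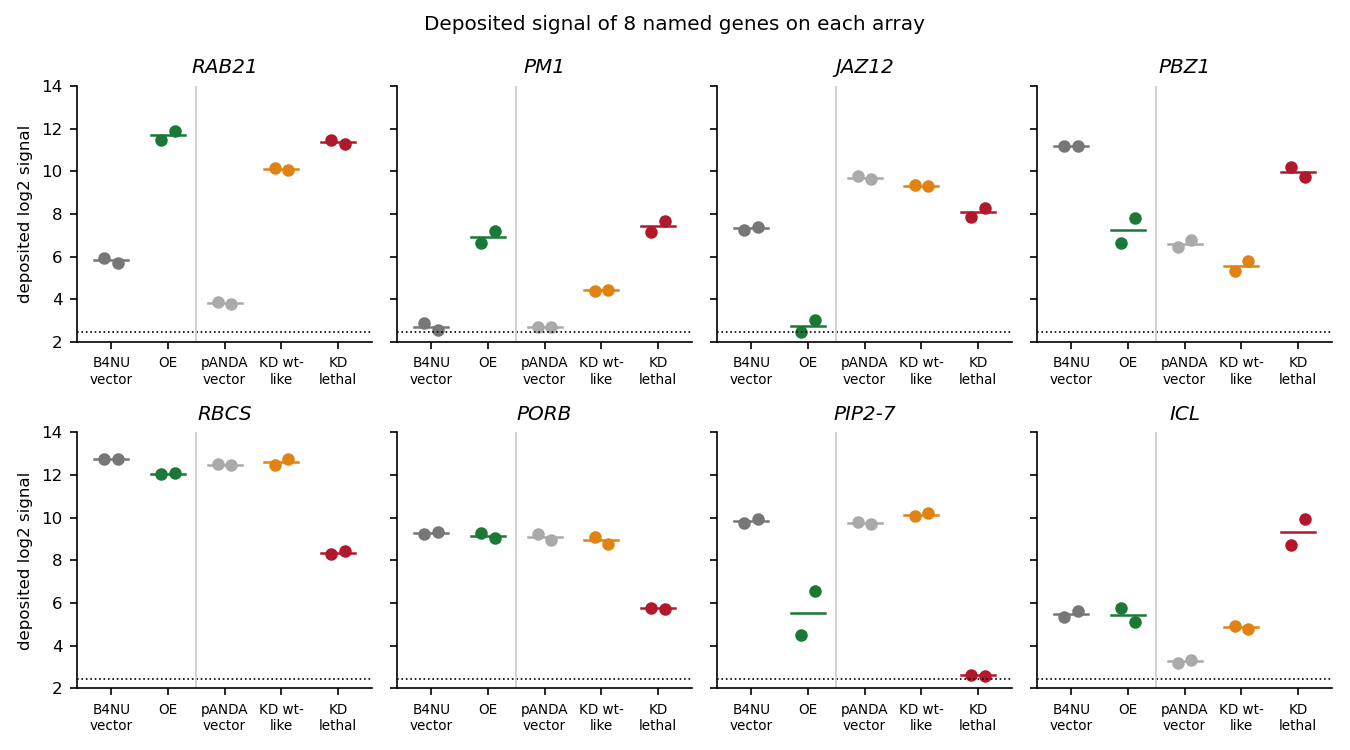
Deposited log2 signal (vertical axis) of 8 genes on each of the 10 arrays, by group (horizontal axis). Points are arrays, bars group means, the dotted line the lowest value on the arrays, and the vertical line parts the separately normalized sets. RAB21 lies at 11.69 in OE against 5.83 in B4NU and at 11.38 in KD lethal against 3.81 in pANDA, while RBCS lies at 8.37 in KD lethal against 12.49 in pANDA.

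KD lethal seedlings were compared with pANDA seedlings to ask which transcripts differ when knock-down has a lethal phenotype. Photosynthesis and chlorophyll genes were lower. Of 14 light reaction genes, 11 fell, 0 rose and the median was -2.84 (camera adjusted p = 6.73e-05, and adjusted p = 0.655 with an estimated correlation). Of 12 Calvin cycle and photorespiration genes, 9 fell and the median was -2.63 (adjusted p = 0.000185, and adjusted p = 0.199 with an estimated correlation). RBCS (LOC4351966), the small subunit of Rubisco, fell from 12.49 to 8.37 ± 0.07 (SD, n = 2), a 17.4-fold difference (adjusted p = 3.58e-05), and the chloroplast glutamine synthetase gene GS2 (LOC4337272) fell by 3.99 ± 0.26 (log2, SE). Of 14 chlorophyll biosynthesis genes, 10 fell and the median was -2.31 (adjusted p = 2.25e-07, and adjusted p = 0.179 with an estimated correlation). Among them, CHLP (LOC4330711), a geranylgeranyl reductase gene, fell 10.3-fold, and PORB (LOC4349004), a protochlorophyllide reductase gene, fell 10.2-fold. Of 27 chloroplast biogenesis genes, 8 fell and 1 rose (median -0.86, adjusted p = 0.00108, and adjusted p = 0.734 with an estimated correlation), including GLK1 (LOC4340977), a regulator of chloroplast development, which fell by 1.35 ± 0.08.

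Among 30 expansin and xyloglucan enzyme genes, which act on the growing cell wall, 8 fell and 1 rose in KD lethal (median -0.71, adjusted p = 0.00045, and adjusted p = 0.179 with an estimated correlation), and EXP5 (LOC4330706) fell 5.60-fold. The falls of largest size included the aquaporin gene PIP2-7 (LOC4347729), at the floor in KD lethal and at least 141-fold lower. The nicotianamine synthase genes NAS1 and NAS2 fell at least 89.6-fold and 46.3-fold, the silicon transporter gene Lsi2 (LOC4331328) fell by 5.29 ± 0.50, and GDCSH (LOC4349114), a subunit gene of glycine decarboxylase, fell by 5.44 ± 0.21. The metallothionein gene MT-1-4b and the peroxiredoxin gene PRXIIE-2 fell 62.6-fold and 55.0-fold. Of 42 genes of the root-linked metal and silicon uptake list, 12 fell and 5 rose. The list did not pass camera (adjusted p = 0.113) but passed with fry as lower (adjusted p = 0.00322). Of 10 seed storage genes none was called, and 7 were at the floor in both groups. Their list did not pass camera (adjusted p = 0.395) but passed with fry as lower (adjusted p = 0.00131).

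RAB21 was also the gene with the largest rise in KD lethal among those the rule names, at 11.38 ± 0.13 against 3.81 ± 0.06 in pANDA, a 190-fold difference (adjusted p = 3.99e-05). Of the 9 dehydration genes, 5 rose and 0 fell (median 3.27, camera adjusted p = 0.000767, and adjusted p = 0.734 with an estimated correlation), including PM1 (at least 26.3-fold) and SALT (LOC4326471; 17.9-fold). Other large rises were ICL (LOC4343441), which encodes isocitrate lyase of the glyoxylate cycle, by 6.07 ± 0.43, OsPP2C45 (LOC4337276), a protein phosphatase 2C gene, by 5.98 ± 0.27, the laccase gene LAC24 (43.1-fold) and the transcription factor gene NAC45 (33.8-fold). Of 16 proteasome genes, 7 rose and 0 fell (median 1.03, adjusted p = 0.000985, and adjusted p = 0.734 with an estimated correlation), for example PAE1 (LOC4350922; 3.60-fold) and RPN11 (2.28-fold). PHYB (LOC4332623), a phytochrome gene, rose 4.44-fold, and the gibberellin 20-oxidase gene GA20OX3 rose 5.85-fold. The flowering-time genes HD16, EHD4 and HD1 rose 2.79-fold, 3.66-fold and at least 1.54-fold, whereas DTH7 and DTH8 fell 1.75-fold and at least 1.53-fold, and of these HD16, EHD4, HD1 and DTH7 lost their calls without either pANDA array.

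In all, 7000 of 57258 probe sets were called in KD lethal, 3909 higher and 3091 lower, and 5179 of them differed at least 2-fold. The count was 2786 when only the 4 arrays of these groups were fitted and 12596 without KD lethal replicate 2 and OE replicate 1. Without pANDA replicate 1 or 2 the split turned, to 1977 higher and 3220 lower or 2000 higher and 2959 lower. Of the 10 named and called genes with a further probe set, 3 had one called the same way, 7 had none called and 0 had one called the opposite way.

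**Figure D2:**
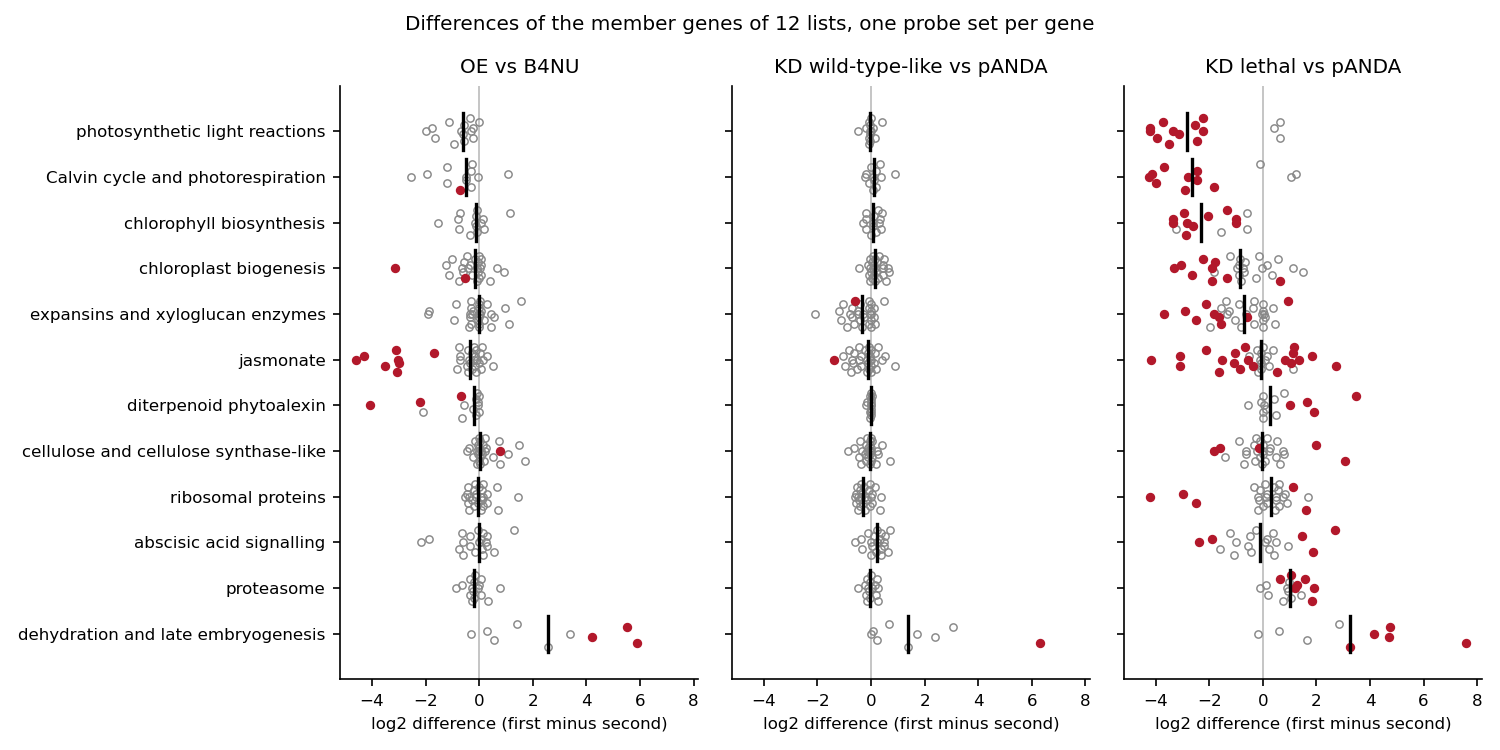
Log2 difference (horizontal axis) of each member gene of 12 gene lists (vertical axis) in OE against B4NU and in both KD groups against pANDA, 1 probe set per gene. Filled points passed adjusted p under 0.05, open points did not, and black bars are list medians. The light reaction genes have a median of -2.84 in KD lethal and -0.04 in KD wild-type-like, and the dehydration genes have medians of 2.58, 1.4 and 3.27 in OE, KD wild-type-like and KD lethal.

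KD wild-type-like seedlings lay closer to pANDA. RAB21 rose by 6.32 ± 0.16 (log2, SE), to 10.12 ± 0.07 (SD, n = 2) from 3.81 (adjusted p = 0.000414), while its other probe set was not called. It was the 1 called gene among the 9 of the dehydration list, whose median was 1.4 (camera adjusted p = 2.82e-07, and adjusted p = 0.844 with an estimated correlation). BURP16 (LOC4348595) rose 4.03-fold and OsC3H37 rose 2.74-fold. The chitinase gene Cht6 (LOC4329920) fell 4.19-fold, JAZ9 (LOC4331832) fell 2.58-fold and DREB1G (LOC4330306), an AP2-type transcription factor gene, fell 2.13-fold. Of these, BURP16, OsC3H37 and Cht6 lost their calls without either B4NU array, and OsC3H37 and Cht6 without either OE array. Against B4NU instead of pANDA, Cht6, JAZ9 and DREB1G were higher in KD wild-type-like, by 2.00, 1.30 and at least 4.44 (log2), and BURP16 had a difference of -0.10 that was not called. Of the 30 expansin and xyloglucan enzyme genes, 1 fell (median -0.33, adjusted p = 2.31e-05, and adjusted p = 0.173 with an estimated correlation), EXP29, which was at the floor in the KD seedlings. Of the 33 jasmonate genes, 1 fell (median -0.11, adjusted p = 0.00139, and adjusted p = 0.844 with an estimated correlation). The chloroplast biogenesis list (median 0.14, adjusted p = 0.0269, and adjusted p = 0.907 with an estimated correlation) and the abscisic acid signalling list (median 0.22, adjusted p = 0.0400, and adjusted p = 0.907 with an estimated correlation) lay higher, and the ribosomal protein list lower (median -0.28, adjusted p = 0.0320, and adjusted p = 0.965 with an estimated correlation), with 0 single genes called. These 3 lists no longer passed without either KD lethal array. The photosynthesis lists did not pass (adjusted p = 0.922 for the light reactions).

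In all, 139 of 57258 probe sets were called in KD wild-type-like, 56 higher and 83 lower. Of these, 49 differed at least 2-fold, and 59 had both groups at the floor. The count was 20 with only the 4 arrays of these groups (RAB21 then no longer passed), 67 without either B4NU array, 257 without either OE array and 230 without the arrays that stood apart. It was 1233 (96 higher and 1137 lower) and 986 (75 and 911) without pANDA replicates 1 and 2, and turned to mostly higher, 2380 (2140 and 240) and 1668 (1506 and 162), without KD wild-type-like replicates 1 and 2.

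The knock-down phenotypes were also compared directly. KD lethal seedlings were lower than KD wild-type-like seedlings in the same photosynthesis lists: 11 of 14 light reaction genes (median -2.84, adjusted p = 1.51e-05, and adjusted p = 0.548 with an estimated correlation), 9 of 12 Calvin cycle genes (median -3, adjusted p = 2.97e-05, and adjusted p = 0.214 with an estimated correlation) and 10 of 14 chlorophyll biosynthesis genes (median -2.25, adjusted p = 3.83e-08, and adjusted p = 0.170 with an estimated correlation) fell. RBCS fell by 4.25 ± 0.09 and GLUTR (LOC4349044), a glutamyl-tRNA reductase gene, fell by 3.32 ± 0.24 (log2, SE). Of the chloroplast biogenesis genes 8 fell and 0 rose (median -1.01, adjusted p = 4.84e-05, and adjusted p = 0.556 with an estimated correlation), and of the expansin and xyloglucan enzyme genes 5 fell and 1 rose (median -0.25, adjusted p = 0.0369, and adjusted p = 0.499 with an estimated correlation). In the root-linked uptake list 12 fell and 4 rose (median -0.01, mean -0.67, adjusted p = 0.0485, and adjusted p = 0.882 with an estimated correlation). Among its members, the silicon transporter gene Lsi1 (LOC4330713) fell by 5.21 ± 0.18 and the zinc transporter gene ZIP1 (LOC4326394) at least 20.6-fold. Proteasome genes were higher, with 8 of 16 called and 0 lower (median 1.00, adjusted p = 0.000737, and adjusted p = 0.780 with an estimated correlation). Of the dehydration genes 4 rose (median 1.25, adjusted p = 0.0448, and adjusted p = 0.882 with an estimated correlation), SALT by 3.92 ± 0.30 and RAB21 by 1.25 ± 0.16. PBZ1 rose 21.4-fold and LAC24 rose 47.6-fold.

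In all, 6408 of 57258 probe sets were called between the KD groups, 3708 higher and 2700 lower in KD lethal. The count was 1191 with only the 4 arrays of these groups and 12345 without the arrays that stood apart. Without KD lethal replicate 1, 5 lists passed instead of 8, and the root-linked, dehydration and expansin lists were lost. Without KD wild-type-like replicate 1 or 2 the split turned, to 2597 higher and 4358 lower or 2130 higher and 3582 lower.

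Whether over-expression and lethal knock-down move transcripts in opposite directions was asked of the 533 probe sets called in both. Of these, 382 differed from their own vector control in the same direction, 315 lower in both and 67 higher in both, and 151 (28.3%) in opposite directions. The directions were associated (Fisher's exact test, two-sided, p = 1.67e-16, odds ratio 8.02). The differences correlated at r = 0.31 over all probe sets, which are not independent replicates. Without both arrays that stood apart r was 0.29, but more of the common probe sets were then higher in both than lower in both. The larger share of falls among the agreeing probe sets therefore depended on the arrays used. RAB21 was higher in both. PBZ1 was lower in OE (6.64 and 7.81) than in B4NU (11.2 on both arrays) and higher in KD lethal (10.22 and 9.71) than in pANDA (6.44 and 6.77). Its opposite directions depend on the vectors, since KD lethal lay below B4NU and OE was not called against pANDA. These cross the normalization sets. When each array was left out in turn, the opposite share lay between 24.6 and 38.3%, and with both vector controls pooled it was 9.8% (36 of 368), but OE and KD lethal then share their control arrays, which favours agreement, so that value does not measure it.

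Of the probe sets called in KD lethal and in KD wild-type-like, 102 were common, 15 higher in both, 81 lower in both and 6 opposite. Independent lists would share 3.8 higher and 4.5 lower. Both comparisons use the same pANDA arrays, and 20 simulations of unchanged groups against those arrays gave a median of 31.5 common probe sets and at most 44. The log2 differences had a correlation of 0.242 (median 0.498 in the simulations) and a covariance of 0.0472 (median 0.0142), a difference in covariance of 0.033. As 2 control arrays cannot be divided into groups of 2, part of the excess may come from the shared controls. With B4NU as the control of KD wild-type-like, so that no array is shared, the direction turned (1118 of 1488 opposite, r = -0.303), and with B4NU as the control of KD lethal 19 of 85 were opposite (r = 0.107). Both of these cross the normalization sets. KD wild-type-like correlated with pANDA at r = 0.988, so its difference from B4NU is close to that of pANDA from B4NU. As pANDA is also the control of KD lethal, the first of these settings favours opposite directions. Its value therefore does not measure whether the KD groups share changes. Leaving out pANDA replicate 1 or 2 raised the count with the same direction from 96 to 1166 or 929, and leaving out KD wild-type-like replicate 1 or 2 raised it to 210 or 178. It was 171 without either OE array and 51 without either B4NU array.

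The vector controls were compared with each other as a background. The cold-response transcription factor genes DREB1B (LOC4347618) and DREB1G were at the floor in B4NU and at least 98.8-fold and 46.2-fold higher in pANDA (adjusted p = 2.23e-05 and 8.49e-07). BHLH148 (LOC4334060) was 44.3-fold higher in pANDA. PBZ1, CYP701A8 and CYP71Z7 were lower in pANDA, by 24.1-fold, 22.3-fold and at least 15.3-fold, and these 3 genes were also lower in OE than in B4NU. The jasmonate list (8 higher and 4 lower of 33, median 0.08, adjusted p = 0.000216, and adjusted p = 0.456 with an estimated correlation), the expansin list (median 0.03, adjusted p = 0.0137, and adjusted p = 0.456 with an estimated correlation) and the abscisic acid list (median 0.04, adjusted p = 0.0137, and adjusted p = 0.553 with an estimated correlation) lay higher in pANDA. The proteasome list lay lower (median -0.52, adjusted p = 0.0137, and adjusted p = 0.920 with an estimated correlation). Of the 14 diterpenoid phytoalexin genes, 4 were lower and 0 higher in pANDA (median -0.22). That list did not pass camera (adjusted p = 0.107) but passed with fry (adjusted p = 0.00295).

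In all, 5610 of 57258 probe sets were called between the vectors, 1628 higher and 3982 lower in pANDA. Of these, 3437 differed by under 0.5 (log2), 3140 had both groups at the floor, and 1122 differed at least 2-fold. The count was 2408 after median centring, 19228 with only the 4 vector arrays, 10891 without either OE array, and 3680 and 3651 without B4NU replicates 1 and 2. The split moved to 2076 higher and 1768 lower after quantile normalization. The vectors lie in different normalization sets, so vector and normalization set cannot be told apart.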

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

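The tests of OE replicate 1, of the array of KD lethal replicate 2, of the abundant root-linked genes and of the 2-fold differences between the vectors, including their sorted values, were chosen only after the result was seen, and the others were written before. The test of KD lethal replicate 2 replaced one written before, the share of called probe sets in which replicate 1 alone lay on the side of the call, which came out at 100% but is void because those probe sets had been chosen for the difference.

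OE replicate 1 stood apart from OE replicate 2, and the balance of the calls differed without either of them (615 of 802 lower with both, 1636 of 2645 higher without replicate 1, 7139 of 12772 higher without replicate 2). Degraded seedling RNA would raise the 3' end over the 5' end. The mean difference of 3 transcripts was instead lower by 1.96 in replicate 1 than in replicate 2 (a difference of -1.96). The bacterial spike bioD, added after labelling, shifted the same way. Its 3' minus 5' signal was -1.08 in OE replicate 1 and -0.41 in KD lethal replicate 2, against 0.47 to 1.03 on the other arrays. This balance is therefore not set by the seedling RNA alone and cannot decide on degradation. Hybridization or scanning of single arrays stays open, and the bioD shift on the arrays that stood apart goes with it. The bacterial spikes added after labelling deviated with an SD of 0.72 in OE replicate 1 against 0.12 to 0.39 on the other arrays. That was short of the doubling over 0.39 that was asked for. Their deviations correlated at 0.69 with those of KD lethal replicate 2, but also at 0.55 with those of KD wild-type-like replicate 1, which did not stand apart. A difference between the seedlings of the replicates was not tested.

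KD lethal differed from pANDA in 7000 probe sets. The array of KD lethal replicate 2, which had an unusual 3' to 5' balance, is argued against as the whole source, since 68.5% of these probe sets were called the same way without it. These probe sets were chosen with both arrays, which favours a high share. More seed remnant with seed storage transcripts in the lethal seedlings is argued against too. The 10 seed storage genes had a median change of 0, none was called, and 8 were at the floor in KD lethal. With 7 of them at the floor in both groups, a remnant without such transcripts would not be seen. The bound written before was a median under 0.5, and a further condition, that no gene rose by 1 or more, was added to it. A larger share of root was not excluded: the root-linked uptake list had a median change of 0 with 10 of 42 genes at the floor in both groups, and its 15 genes with a mean above 6 in either group had a median of -1.42 (bootstrap SE 1.24), short of the 2 SE under 0 that were asked for. Values that go against it are the 5 genes above 8, with a median of -5.29 (SE 1.70), 4 of them called lower and 1 higher. The whole list also passed with fry as lower (adjusted p = 0.00322), though not with camera. An effect of the lethal phenotype itself stays open and untested.

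The vectors differed in 5610 probe sets. Different value distributions of the normalization sets remain open for the whole count: quantile normalization kept 68.5% of the count, just past the bound of 67% set before for excluding them, but this share lay between 34.5 and 73.0% when each array was left out, and median centring kept 42.9% (conditions on centring, and then in its place on left-out arrays, were added after the value was seen, and under both the question stayed open). They are argued against as the whole source of the 1122 differences of at least 2-fold, since the sorted values of the vectors lay at most 0.29 apart (at most 0.18 between replicates), although 71.7% were called the same way after quantile normalization and 84.9% after median centring, short of the 90% first asked for. The 317 no longer called after quantile normalization had a median size of 1.18 before (SE 0.20) and 0.97 after (SE 0.29), so the difference shrank while its SE grew. Differences between seedlings of the vectors lie along the same line as the sets and cannot be told apart from them.

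The control probe sets lie outside the main measurement, and 2 of their means exceeded the higher array of the own vector by more than 0.5 and by more than the vector arrays differed. The 5 ribosomal RNA probe sets had a mean log2 signal of 7.68 in OE replicate 1, against 5.98 and 6.65 in B4NU and 3.05 in OE replicate 2. The 27 probe sets of bacterial spikes added after labelling had a mean of 8.91 in KD wild-type-like replicate 2, against 7.27 and 7.45 in pANDA and 7.84 in KD wild-type-like replicate 1. The 36 probe sets of bacterial poly(A) spikes lay lower than in the own vector, at 3.72 and 3.66 in KD lethal against 4.68 and 4.69 in pANDA, and at 3.53 and 3.64 in OE against 4.14 and 4.01 in B4NU.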

How the results depend on the processing

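The fits without both arrays that stood apart, with the 6 arrays of one normalization set, with a ubiquitin covariate and with crossed replicate numbers, the other vector controls for named genes, and the leaving out of arrays for the changes shared by the KD groups, were chosen after seeing the data. The counts of calls depended strongly on which arrays gave the spread, and in 2059 of the repeats for named genes the result of the test stayed, while 279 lost a call, 25 gained one and 19 reversed, all with other vector controls. Most of these genes were named because they were called, and leaving out an array of another group does not change a log2 difference. Few reversals could therefore be expected outside the other vector controls. Lists kept their calls in 325 repeats and lost them in 65. Signal over background limits the rest, since about 65.6 to 68.8% of values lay near the floor.

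The main counts were 802 for OE, 7000 for KD lethal, 139 for KD wild-type-like, 6408 between the KD groups and 5610 between the vectors. With only the 4 arrays of the groups compared, they were 17, 2786, 20, 1191 and 19228, with fewer degrees of freedom, and the count for the vectors rose all the same. The main fit takes 1 spread per probe set from all groups. Replicates differed with an SD of 0.118 in B4NU, 0.133 in pANDA, 0.214 in KD wild-type-like, 0.341 in KD lethal and 0.58 in OE. The main p-values for OE therefore rest partly on tighter groups, and those for the vectors on wider ones. Without both arrays that stood apart, OE had 4003, KD lethal 12596, KD wild-type-like 230 and the KD groups 12345. In the upper part of the probe sets by mean, OE had 1403, KD wild-type-like 91 and the vectors 2703. With 1 probe set per gene, KD wild-type-like had 76 and the vectors 1846, and with a 2-fold cutoff they had 49 and 1122. Quantile normalization gave 219 for KD wild-type-like, and median centring 2408 for the vectors. Quantile normalization also turned the split between the vectors (2076 higher and 1768 lower). With the other vector as control, OE had 7865 (5027 higher and 2838 lower, against 187 and 615), KD wild-type-like 5756 (1562 and 4194, against 56 and 83) and KD lethal 10380 (3810 and 6570, against 3909 and 3091), and with both vectors pooled KD wild-type-like had 37; these cross the normalization sets. The 6 arrays of its set gave 83 for KD wild-type-like. The cause was not tested.

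When each array was left out in turn, the counts ran from 349 to 12772 for OE, 4892 to 9546 for KD lethal, 67 to 2380 for KD wild-type-like, 4378 to 8927 between the KD groups and 3651 to 10891 between the vectors. A group left with 1 array is assumed to vary like the other groups. The shared changes in the same direction ran from 51 to 1166 (96 with all arrays), and the opposite share of OE and KD lethal from 24.6 to 38.3%; with both vectors pooled it was 9.8%, but both comparisons then share control arrays, which favours agreement.

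The replicate numbers did not mark a consistent pairing: differences between replicates 1 and 2 correlated at -0.57 (OE and KD lethal) to 0.31 (B4NU and KD lethal). The negative value means that OE replicate 1 deviated along with KD lethal replicate 2, the arrays that stood apart. A factor shared by arrays of different numbers is therefore not excluded, and its cause was not tested. With the number as a replicate block, calls were 423 for OE, 5742 for KD lethal, 49 for KD wild-type-like, 5152 between the KD groups and 4096 between the vectors, and the shared changes were 34. The opposite share was 29.7% with the block. Crossing the numbers gave 471 for OE and 5538 between the KD groups.

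With the estimated correlation, 0 lists passed in OE, KD lethal, KD wild-type-like, between the KD groups and between the vectors, where camera with the preset correlation had passed 5, 7, 6, 8 and 4. Fry passed 17 in KD lethal, 2 in KD wild-type-like and 16 between the KD groups. With arrays left out in turn, lists passing ran from 1 to 7 in OE, 3 to 7 in KD wild-type-like and 5 to 8 between the KD groups. The shared changes were 147 after quantile normalization. With B4NU as the control of KD wild-type-like they reversed: 1118 of 1488 common probe sets were opposite (r = -0.303), and the 370 with the same direction compare with 106.6 higher and 226.4 lower for independent lists. That setting favours opposite directions, since KD wild-type-like lay close to pANDA, the control of KD lethal. The target's alternatives were not run, because OsbZIP48 was not analysed here.

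Log2 differences that reversed with the other vector as control were CYP701A8 0.40 and PBZ1 0.62 in OE. In KD wild-type-like they were Cht6 2.00, JAZ9 1.30, DREB1G at least 4.44, SAP17 1.34 and EXP5 1.07, which passed on the other side. BURP16 -0.10, MS -0.13, GL2 0.08, AOS 0.32, AOS4 0.13 and SAPK10 -0.46 reversed without passing. Also counted above as reversals, by sign alone, were KSL7 in OE (0.13) and TPP4 (0.08), at the floor in both groups and so without order. The same holds for CPSECY, with a difference of 0.00. With both vectors pooled, DREB1G (1.68), SAP17 (0.40) and EXP5 (0.13) reversed in KD wild-type-like without passing. No gene named by the rule reversed in KD lethal. CYP701A8, KSL7 and CM-LOX2, chosen after their values were seen and described below, rose against pANDA but stood lower in KD lethal than in B4NU. These comparisons cross the normalization sets, and the cause was not tested.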

Other observations

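The test of B4NU and that of the dehydration list were chosen only after the result was seen. The genes in the next paragraph were chosen after their values were seen.

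In KD lethal, 4 of the 14 diterpenoid phytoalexin genes rose and 0 fell (median 0.26). The list did not pass camera (adjusted p = 0.166) but passed with fry as higher (adjusted p = 0.000811). The P450 gene CYP701A8, named KOL4 in the list, rose by 3.48 (log2) against pANDA, and KSL7, at the floor in pANDA, rose by at least 1.90, whereas both fell in OE against B4NU. CM-LOX2, a lipoxygenase gene at the floor in OE and in pANDA, fell by at least 3.09 in OE and rose by at least 2.75 in KD lethal. These opposite changes depend on the vectors: in KD lethal the 3 genes stood at 6.45, 4.34 and 5.50, and in B4NU higher, at 7.44, 4.78 and 5.56. Of 33 jasmonate genes in KD lethal, 12 fell and 8 rose. Among 47 heat shock genes 8 rose and 4 fell (adjusted p = 0.395 with camera and 0.0208 with fry, as higher). Among 19 phenylpropanoid and flavonoid genes 2 rose and 6 fell (adjusted p = 0.250 with camera and 0.00507 with fry, as lower).

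A candidate explanation for probe sets lower in OE than in B4NU is that the B4NU seedlings themselves stand high. Of the 615 such probe sets, 40.2% (247) were also lower in pANDA than in B4NU, which lies between the bounds of 50% and 20% and leaves it open. Independent lists would share 42.8, and 20 simulations of unchanged groups against the B4NU arrays gave a median of 47.5 and at most 75. Over both directions in OE, 140 probe sets differed from B4NU in opposite directions in OE and pANDA. PBZ1, CYP701A8 and CYP71Z7 stood higher in B4NU, at 11.2, 7.44 and 6.73, than in pANDA, at 6.61, 2.96 and 2.80. JAZ12, JAZ10 and JAZ9, which also fell in OE, stood lower in B4NU, at 7.32, 6.71 and 5.55, than in pANDA, at 9.71, 11.12 and 8.21. Against pANDA, B4NU was therefore not high for these genes, but whether pANDA itself stands high was not tested. As pANDA lies in the other normalization set, part of these differences may come from the sets.

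The dehydration list stood higher in OE and in both KD groups than in the vector control of each. The lowest of the 3 medians was 1.4 (KD wild-type-like), and camera passed in each with the preset correlation but in none with the estimated one. A shared gain of dehydration transcripts in transgene seedlings may therefore be worth testing, as a hypothesis found and tested on the same data. In KD wild-type-like only RAB21 of the 9 genes was called, and the RAB16 genes may share signal, so the genes are not independent.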
